A study of Mus musculus with 8 samples.

How the data were processed

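RNA was measured on Affymetrix mouse arrays in NIH3T3 cells, an established mouse embryonic fibroblast line. The cells carried fluorescent reporters of p27 and Cdt1. There were 8 arrays, 4 of cells sorted as G0 and 4 of cells sorted as G1, grouped by the titles. The titles number the replicates 1 to 4 in each group. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

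The deposited values are log2 expression values, 1 column per array, and were made with MAS5 per the submitters' processing notes. Each probe set had been centred on its own median over the 8 arrays before deposit, as the values themselves show: the largest absolute probe set median was 5e-07. The step that took logs and centred the values is not given in the sources used here. The log base is not stated either. It was taken as 2, because a lowest value of −12.4 and a highest of 5.58 would be an impossible range in base 10. All folds and log2 differences printed here rest on that reading. Centring leaves differences between arrays intact and removes every absolute level, so dim or saturated probe sets could not be recognised by their level, and a large difference may sit on a low signal. A floor set before centring shows only as ties. In 417 probe sets the lowest value was shared by 2 or more arrays (equal to all digits deposited), and in 116 by 3 or more, while the highest was shared in 0. A probe set with a single value at the floor cannot be recognised. Array medians lay between −0.07 and 0.09, a range of 0.16, and no further scaling was applied. Precision is limited by the number of arrays.

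The table held 45101 probe sets. The 64 manufacturer's control probe sets were left out of the tests, which leaves 45037. Of these, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Symbols were updated through the Entrez identifier for 34741 probe sets, using the gene table of mouse assembly GRCm38.p6. Of that table only names were used. No genome build is named for the array values, so no coordinates are given. The probe sets with 1 symbol stood for 18193 genes, and 9010 genes had more than 1 probe set. The design had planned to represent a gene by its brightest probe set after a filter on level. With centred values neither step was possible. A gene was instead represented by a probe set chosen without regard to the outcome, taking suffixes in the order _at, _a_at, _s_at, _x_at and then the lowest probe set number. No level filter was used.

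Differences were G1 minus G0. They were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, on all 8 arrays. The labelling batch was a covariate, because the labels' protocols say that replicate 4 of each group was labelled with kit protocol revision 3 and another RNA input, and the other replicates with revision 8. The fit had 5 residual degrees of freedom and 2.34 prior ones. P-values were adjusted by the Benjamini-Hochberg method over 45037 probe sets, with a threshold of 0.05. Because the values are centred, the trend follows each probe set's mean about its median, not its brightness. The same fit on simulated arrays, centred in the same way and with 50 probe sets changed at each size among 45037, recovered 54% of changes of 3 log2 units and 70% of changes of 4 units when any probe set could change. It recovered 26% at 2 units and 0% at 1 unit. With the changed probe sets drawn from the quieter part, it recovered 90% at 3 units and 98% at 4 units. The simulations gave 3 false calls among 78 and 7 among 128. They drew errors independently for each probe set, so correlation between genes is not represented.

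The poly-A spike-in controls, bacterial transcripts added to total RNA before labelling, disagreed with the labelled batches. They were missing on the arrays titled G0 replicate 3 and G1 replicate 4, whereas the labels put G0 replicate 4 in the second batch. The planned fit was kept. A fit with the batch that the spike-ins show in place of the labelled batch, and a fit on the 6 arrays with spike-ins, were added after seeing the data. Both batch covariates are balanced between the groups, so the log2 differences of the 8-array fits are identical and only their errors differ. By the titled numbers the replicates did not pair, so no pairs were used.

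There were 27 gene lists, fixed before the data were examined, with 851 list entries, of which 776 were measured. They cover the cell cycle, its inhibitors and p27 degradation, immediate early and growth arrest genes, ribosome biogenesis, ribosomal proteins, translation factors, cholesterol synthesis, glycolysis, nucleotide synthesis, the respiratory chain, p53 targets, lysosome, extracellular matrix, cytokines, interferon-stimulated genes, heat shock, YAP and SRF targets, the circadian clock, and markers of leukocytes, epithelium, endothelium, and muscle and fat. Lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over 27 lists, and again with an estimated correlation. Fry was run beside it. It asks whether a list's genes move on balance one way, or, in its mixed form, in either direction, and does not compare them with other genes.

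The rule for named genes was also fixed beforehand. It always names the CDK inhibitors, Cdkn1b, Cdt1, Mki67, Ccnd1 and Myc. It further allows the other members of the lists of D-type and E-type cyclins and of CDK inhibitors and Rb family genes, the 12 largest rises and the 12 largest falls among genes past the threshold with the same sign in both labelled batches, and up to 4 members of each other list by adjusted p. Not every gene that it allows is named, and the leading member of a list can be among those left out. Genes named outside it are said to be so. Control ratios were compared between the groups with exact permutation tests over 70 assignments. Alternatives covered scaling between arrays, the batch covariate, the replicate block, the variance model, array weights, the choice of probe sets, the correlation used for lists, and each array left out in turn.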

Results

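The cells were NIH3T3 mouse fibroblasts that expressed an mVenus fusion of a p27 mutant and an mCherry fusion of a Cdt1 fragment. P27 is a cyclin-dependent kinase (CDK) inhibitor that is abundant in quiescent cells, and the Cdt1 fragment is present in G0 and G1 and destroyed from S phase on. The cells were starved of serum and returned to 10% serum for 5 h. They were then sorted into p27-positive, Cdt1-positive cells (called G0) and p27-negative, Cdt1-positive cells (called G1). Total RNA of each population was hybridised to 4 arrays. The comparison asks how the transcripts of cells still in quiescence differ from those of cells already in G1 of the same culture regime. Values are log2 expression relative to each probe set's median over the 8 arrays (base taken as 2), so differences between groups are measured and absolute levels are not.

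The transcripts behind the sorting reporters did not differ past the threshold. The log2 difference, G1 minus G0, was −0.56 for Cdkn1b, which encodes p27 (standard error (SE) 0.61, adjusted p = 0.926, n = 4 per group). It was 0.39 for Cdt1, the replication licensing factor (SE 0.20, adjusted p = 0.769). Both genes were used for sorting as protein reporters, and a probe set could read a transgene, so neither value is an independent finding.

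Cells sorted as G1 carried far more mRNA of proliferation genes than cells sorted as G0. Of 18193 genes, 95 differed at an adjusted p under 0.05 in limma, 91 higher in G1 and 4 lower, all of them by at least 2-fold. At an unadjusted p under 0.05 there were 1468, in either direction. A few members of a list at that p are therefore no sign of a shift by themselves. Mki67, the gene of the Ki-67 proliferation antigen, was 14.2-fold higher in G1, at −1.94 ± 0.38 in G0 and 1.88 ± 0.28 in G1 (SD, n = 4; log2 difference 3.82, SE 0.25, adjusted p = 0.0089). Birc5 (survivin, a subunit of the chromosomal passenger complex) was 11.1-fold higher (log2 difference 3.47, SE 0.21, adjusted p = 0.0089). The kinase of that complex, Aurkb, was 11.3-fold higher (log2 difference 3.50, SE 0.28, adjusted p = 0.010). In all 95 genes the 4 G1 values lay wholly on the same side of the 4 G0 values. Of all genes tested 7.07% were separated in this way, where chance gives 2.86%.

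The largest rise was that of Bard1, the partner of Brca1 in DNA repair, at 17.5-fold (log2 difference 4.13, SE 0.56, adjusted p = 0.037). Esco2, which acetylates cohesin in S phase, rose 14.6-fold (3.87, SE 0.42, adjusted p = 0.018). Among the 12 largest rises were also Ndc80, a kinetochore protein (9.30-fold), the kinases Pbk (9.52-fold) and Melk (9.25-fold), and Shcbp1 (12.7-fold). The others were Ltb, which encodes the cytokine lymphotoxin beta (9.54-fold), and the uncharacterised genes 2410003I16Rik and 4930503B20Rik (11.6-fold). The rise of 2410003I16Rik, 14.1-fold as deposited, has no exact size or rank. It read the same lowest value, −2.20, on G0 replicates 2, 3 and 4, as at a floor. No other of the 95 genes had tied lowest values. Its only probe set also had the _x_at suffix, which marks possible cross-hybridisation.

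Only 4 genes fell in G1. Galns, a lysosomal sulfatase, was 14.8-fold lower (log2 difference −3.88, SE 0.51, adjusted p = 0.031). Its other probe set differed by 0.30 with the opposite sign (adjusted p = 0.900). Of the 45 genes past the threshold with more than 1 probe set, 38 had the same sign on all of them, and 0 had another probe set past the threshold in the opposite direction. For 4930503B20Rik and Rrm1, 2 of 3 probe sets were positive and 1 passed. Lgi4, a secreted protein of glial cells, was 8.05-fold lower (−3.01, SE 0.35, adjusted p = 0.021). Odam was 5.89-fold lower (−2.56, adjusted p = 0.0499) and 0610006L08Rik 5.18-fold lower (−2.37, adjusted p = 0.025).

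The count of genes past the threshold depended on the error estimate and on single arrays. With the batch that the spike-in controls show as covariate, chosen after seeing the data, 183 genes passed (169 higher, 14 lower) and 94 of the 95 were among them. The exception was 0610006L08Rik (adjusted p = 0.064). On the 6 arrays with spike-ins, 31 genes passed (30 higher, 1 lower). In limma fits that left out a single array, 28 genes passed without G0 replicate 1 and 67 without G0 replicate 3. With any of the other 6 left out (G0 replicate 2 or 4, or G1 replicate 1, 2, 3 or 4) 0 genes passed, with 1332, 1658, 1267, 1255, 1284 and 1622 genes at an unadjusted p under 0.05. The fit on all 8 arrays had 1468. Without replicate 4 of either group, the batch term absorbs the other array of labelled batch 2. Those fits then compare labelling batch 1 only, so they are not separate results for single arrays. With the spike-in batch as covariate instead, leaving out G0 replicates 1 to 4 in turn gave 128, 108, 58 and 92 genes, and leaving out G1 replicate 2 gave 36. Without G1 replicate 1, 3 or 4 that fit gave 0 genes in limma, with 2090, 1938 and 1677 at an unadjusted p under 0.05. Without G0 replicate 3 or G1 replicate 4 that fit takes the difference from the 6 arrays with spike-ins only. In each of the 8 fits with the labelled batch all 95 genes kept their direction and differed by at least 2-fold. They did so too within each labelled batch and within each batch that the spike-ins show. By the spike-ins, the G0 and G1 arrays of labelled batch 2 were labelled differently, so differences within it cannot be told apart from labelling. The direction was fixed by the choice of genes, since all 95 separate the groups completely on these arrays. The sizes come from the arrays that chose the genes, so neither tests stability. A batch of 1 array per group gives no test.

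**Figure D1:**
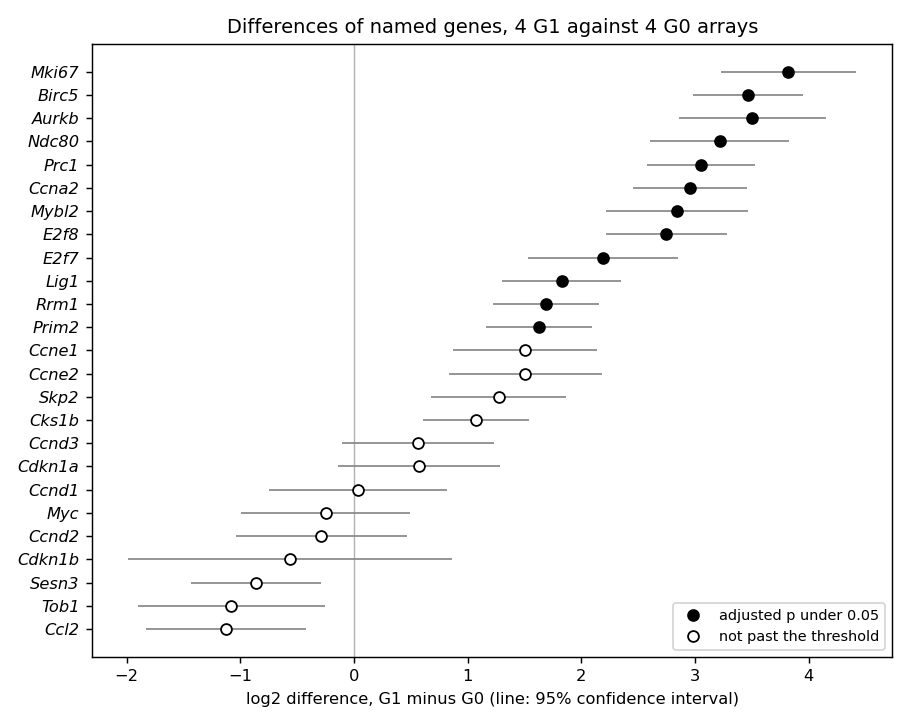
Log2 difference of named genes, G1 minus G0 (horizontal axis, log2 units), with 95% confidence intervals from limma on 4 arrays per group. Filled points passed an adjusted p of 0.05. Genes of mitosis and S phase, from Mki67 at 3.82 to Prim2 at 1.63, lie above 0 with intervals that exclude it, while Ccnd1, Myc and Cdkn1b have intervals that include 0.

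Genes of G2 and mitosis rose most as a group. Of 49 measured members, 24 were higher in G1, 0 were lower, and 25 did not pass the test. Adjusted over the list alone, 42 were higher. With the spike-in batch as covariate 34 were higher over all genes, and on the 6 arrays with spike-ins 13 were. No member was lower at an unadjusted p under 0.05 in limma, and 43 were higher. The median log2 difference was 2.32, a 4.98-fold rise (camera, adjusted p = 6.25e-72; adjusted p = 0.034 with an estimated correlation). Prc1, which bundles the microtubules of the central spindle, was 8.30-fold higher (log2 difference 3.05, SE 0.20, adjusted p = 0.0089). Ccna2, the S and G2 phase cyclin A2, was 7.77-fold higher (2.96, SE 0.21, adjusted p = 0.0089). The list's median per array ran from −1.51 to −0.94 in G0 and from 0.86 to 1.52 in G1. Within the labelled batches the median differences were 2.27 and 2.48, and within the batches shown by the spike-ins 2.27 and 2.41.

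The list of replication licensing and S phase genes also rose. Of 49 measured members, 9 were higher and 40 did not pass over all genes tested. Adjusted over the list alone, 38 were higher, and with the spike-in batch as covariate 26 were higher over all genes, but on the 6 arrays with spike-ins only 1 was. All 49 members had a positive difference, with a median of 1.20 (2.30-fold; camera, adjusted p = 4.09e-51; adjusted p = 0.027 with an estimated correlation). Lig1, the ligase that joins Okazaki fragments, was 3.55-fold higher (log2 difference 1.83, SE 0.22, adjusted p = 0.025), and Rrm1, a subunit of ribonucleotide reductase, was 3.23-fold higher (1.69, SE 0.20, adjusted p = 0.022). The mean of Rrm1's probe sets differed by only 0.87 (limma, adjusted p = 0.736). The primase subunit gene Prim2 was 3.09-fold higher (1.63, SE 0.20, adjusted p = 0.025). Within the labelled batches the list's median was 1.14 and 1.27, and within the spike-in batches 1.24 and 1.19.

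Among the 20 E2F and DREAM complex genes, which control transcription of the cell cycle genes, 3 rose and 17 did not pass. The repressor E2f8 was 6.72-fold higher (2.75, SE 0.23, adjusted p = 0.010), E2f7 was 4.58-fold higher (2.19, SE 0.28, adjusted p = 0.030) and Mybl2 (B-Myb) was 7.17-fold higher (2.84, SE 0.27, adjusted p = 0.011). Adjusted over the list alone 7 rose, and 1 passed over all genes on the 6 arrays with spike-ins. With the spike-in batch as covariate, 9 were higher and 1 lower when adjusted over the list alone. The list's median was 0.65 (camera, adjusted p = 6.36e-07), and this call was lost with an estimated correlation (adjusted p = 0.124). It was 0.56 and 1.35 within the labelled batches and 0.74 and 0.66 within the spike-in batches. In the 3 lists above and that of D-type and E-type cyclins, 36 of the 133 genes were among the 91 higher in G1 (27.1%, against 0.305% of the other genes tested; Fisher's exact test, two-sided, p = 1.51e-54). Genes are not independent replicates, so this p describes the overlap, not the spread between samples.

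**Figure D2:**
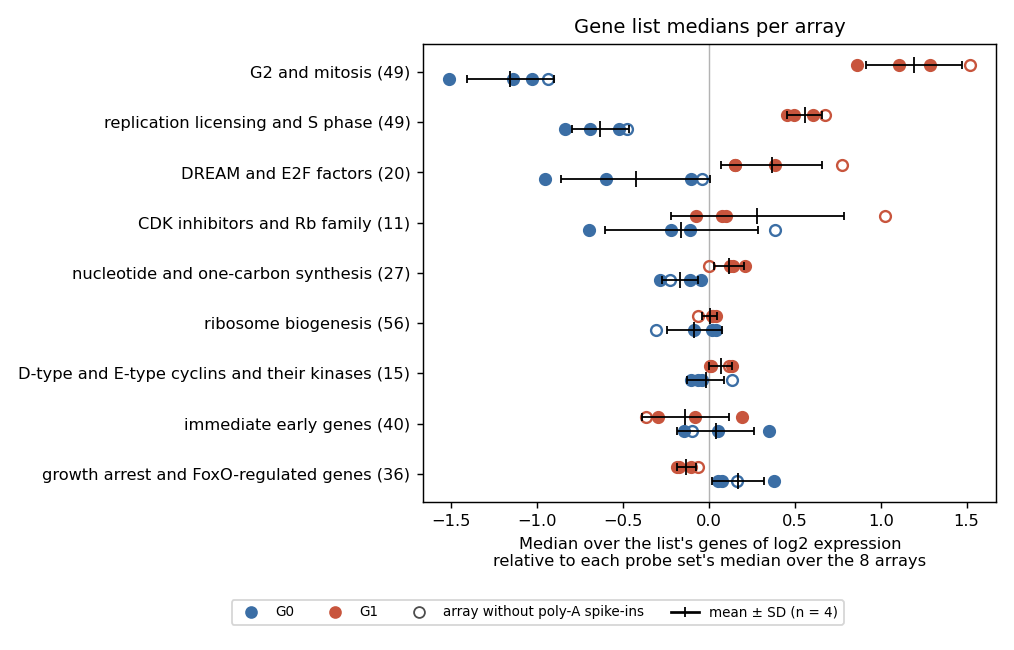
Median over each list's genes of the log2 value relative to the 8-array median (horizontal axis), for each array of G0 (blue) and G1 (red), with the number of measured genes in brackets. Black marks give the mean ± SD of the 4 arrays, and open circles the 2 arrays without poly-A spike-ins. For the G2 and mitosis list the G1 arrays lie at 0.86 to 1.52 and the G0 arrays at −1.51 to −0.94, while the 2 groups overlap for the immediate early genes.

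None of the 15 genes in the list of D-type and E-type cyclins and their kinases passed over all genes tested in limma. At an unadjusted p under 0.05, 3 did. The list as fixed also held Mnat1, Cdk7, Ccnh, Ccnc and Cdk8, so its counts and median do not describe those cyclins and kinases alone. Adjusted over the list alone, 2 were higher. The E-type cyclins Ccne1 and Ccne2, which activate Cdk2 at the G1 to S boundary, differed by 1.50 (SE 0.27, adjusted p = 0.113) and 1.51 (SE 0.29, adjusted p = 0.132). Both passed with the spike-in batch as covariate (adjusted p = 0.0060 and 0.019). Ccnd1, cyclin D1, differed by 0.04 (95% confidence interval −0.75 to 0.82), Ccnd2 by −0.29 (−1.04 to 0.46) and Ccnd3 by 0.56 (−0.10 to 1.23). With the spike-in batch as covariate the intervals of Ccnd2 (−0.56 to −0.01) and Ccnd3 (0.14 to 0.98) excluded 0. That of Ccnd1 (−0.39 to 0.46) did not. Neither Ccnd2 nor Ccnd3 passed in that limma fit (adjusted p = 0.424 and 0.309). Cdk4 and Cdk6 differed by 0.32 and 0.04, and the phosphatase Cdc25a by 0.76 (adjusted p = 0.430). Cdk2 differed by 0.08 with a 95% confidence interval of −2.87 to 3.02, too wide to read. The list's median was 0.04 (camera, adjusted p = 0.145). Fry, which does not compare the list with other genes, placed it higher (adjusted p = 0.014; mixed form, adjusted p = 0.0014). The median was 0.18 and 0.29 within the labelled batches and −0.02 and 0.19 within the spike-in batches. Its median was −0.18 without G0 replicate 3 and −0.01 without G1 replicate 3.

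Among 11 CDK inhibitors and Rb family genes, 0 passed in limma over all genes or over the list alone, and 2 were higher at an unadjusted p under 0.05. These were Rbl1 (p107) at 0.83 (adjusted p = 0.432) and Cdkn3 at 0.82 (adjusted p = 0.391). With the spike-in batch as covariate, 2 genes were higher when adjusted over the list alone. Cdkn1a (p21) differed by 0.57 (adjusted p = 0.771), Cdkn2d (p19) by 1.12 (adjusted p = 0.703) and Cdkn1c (p57) by −1.17 (adjusted p = 0.890). Cdkn2a, Cdkn2b and Cdkn2c differed by 0.77, 0.78 and 0.04 (adjusted p = 0.922, 0.946 and 0.990). Cdkn2a scattered widely, with an SD of 1.86 in G0 and 1.43 in G1, as did Cdkn2b (1.47 and 1.52). Neither value can be read as a change, and without absolute levels these values do not show whether these genes were expressed at all. The list's median of 0.57 passed camera (adjusted p = 0.036) but not with an estimated correlation (adjusted p = 0.503). The call was lost without G0 replicate 1, 2 or 4 or G1 replicate 1 or 4 (adjusted p = 0.052, 0.142, 0.216, 0.091 and 0.218), in labelling batch 1 alone (0.218) and with the mean of all probe sets (0.079). The medians within the labelled batches were 0.30 and 1.21, and within the spike-in batches 0.39 and 0.38. With 11 genes such a median is the value of a single gene. The 1.21 is that of Cdkn2b and the 0.39 that of Cdkn2a, so they are uncertain.

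Of 17 genes of p27 degradation, 0 passed over all genes tested in limma, 3 were higher at an unadjusted p under 0.05, and the same number were higher adjusted over the list alone. These were Skp2, the F-box protein that binds phosphorylated p27 (1.27, SE 0.25, adjusted p = 0.159), its cofactor Cks1b (1.08, SE 0.20, adjusted p = 0.120) and Cks2 (1.24, SE 0.22, adjusted p = 0.113). With the spike-in batch as covariate Cks1b and Cks2 passed (adjusted p = 0.039 and 0.031), and Skp2 did not (adjusted p = 0.057). Camera placed the list higher (adjusted p = 0.042; adjusted p = 0.204 with an estimated correlation), while its median was −0.02 and its mean 0.19. The camera call was lost without G0 replicate 1, 3 or 4 or G1 replicate 1, 3 or 4 (adjusted p = 0.074, 0.060, 0.139, 0.084, 0.071 and 0.138), on the 6 arrays with spike-ins (adjusted p = 0.116), in labelling batch 1 alone (0.137), with the replicate block (0.064), with array weights (0.057), with the mean of all probe sets (0.114) and with the quietest probe set (0.093). The median was −0.06 and 0.27 within the labelled batches and −0.03 and 0.17 within the spike-in batches.

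No gene of the 36 growth arrest and FoxO-regulated genes passed by itself in limma over all genes tested, with 5 lower and 0 higher at an unadjusted p under 0.05. Adjusted over the list alone, 0 passed with the labelled batch. With the spike-in batch as covariate, 9 were lower and 1 higher over the list alone. As a group they lay lower in G1, with a median of −0.36 (camera, adjusted p = 0.00042), and 32 of the 36 had a difference of 0 or less. The call was lost with an estimated correlation (adjusted p = 0.204). The antiproliferative factor Tob1 differed by −1.08 (SE 0.35, adjusted p = 0.525), Zfp36l1, an mRNA decay factor, by −0.88 (SE 0.25, adjusted p = 0.413), and Sesn3, a FoxO target that restrains mTORC1, by −0.86 (SE 0.24, adjusted p = 0.410). Selenop differed by −0.84 (SE 0.21, adjusted p = 0.298). Within the labelled batches the list's median was −0.38 and −0.15, and within the spike-in batches −0.34 and −0.47.

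Immediate early genes, the first to respond to serum, did not pass as a group (median −0.25; camera, adjusted p = 0.132). Of 40 members 0 passed in limma and 2 were lower at an unadjusted p under 0.05, the phosphatase gene Dusp1 (−0.77, SE 0.28, adjusted p = 0.619) and Klf10 (−0.49, SE 0.20, adjusted p = 0.661). The list passed as lower without G0 replicate 1 (median −0.27, adjusted p = 0.042), G0 replicate 3 (−0.33, adjusted p = 0.018) or G1 replicate 2 (−0.29, adjusted p = 0.031). Within the labelled batches the median was −0.21 and −0.55, and within the spike-in batches −0.16 and −0.36. Myc, a growth regulator induced by serum, differed by −0.25 (95% confidence interval −0.995 to 0.496, adjusted p = 0.945). Of 56 ribosome biogenesis genes 0 passed in limma, and 0 did at an unadjusted p under 0.05. The median was 0.09 (camera, adjusted p = 0.072), and the list passed as higher without G0 replicate 2 (median 0.14, adjusted p = 0.0060), G0 replicate 4 (0.18, adjusted p = 0.0018) or G1 replicate 4 (0.18, adjusted p = 0.0013), and with the spike-in batch as covariate (adjusted p = 0.022, but 0.601 with an estimated correlation). Within the labelled batches the median was 0.18 and −0.09, and within the spike-in batches 0.08 and 0.22. Polr1b, a subunit of RNA polymerase I, differed by 0.52 (SE 0.29, adjusted p = 0.783).

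Nucleotide and one-carbon synthesis genes lay higher in G1. The median over 27 genes was 0.33, a 1.26-fold difference (camera, adjusted p = 2.71e-06; adjusted p = 0.036 with an estimated correlation). None passed by itself in limma over all genes tested, and 5 were higher and 0 lower at an unadjusted p under 0.05. With the spike-in batch as covariate, 4 were higher when adjusted over the list alone. Shmt1, which makes one-carbon units from serine, differed by 0.80 (SE 0.22, adjusted p = 0.397), Mthfd1 by 0.63 (SE 0.20, adjusted p = 0.520) and Prps1 by 0.54 (SE 0.18, adjusted p = 0.553). The list's median was 0.33 and 0.20 within the labelled batches and 0.31 and 0.29 within the spike-in batches.

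The other 4 lists past camera's threshold were lower in G1, and all lost the call with an estimated correlation. No member of them passed alone in limma over all genes tested. With the spike-in batch as covariate, 1 cytokine gene was lower when adjusted over its list alone. Lysosome and autophagy genes had a median of −0.24 (adjusted p = 0.0051; adjusted p = 0.499 with an estimated correlation; 3 of 41 lower at an unadjusted p under 0.05), with the protease gene Ctso at −1.06 (SE 0.30). Extracellular matrix genes had a median of −0.29 (adjusted p = 0.019; adjusted p = 0.204 with an estimated correlation; 3 of 47), with Ogn (osteoglycin) at −1.75 (SE 0.38, adjusted p = 0.208) and Col3a1 at −0.72 (SE 0.21). This call was lost without G0 replicate 2 or 4 or G1 replicate 1 or 4 (adjusted p = 0.074, 0.124, 0.083 and 0.108) and in labelling batch 1 alone (0.111). Cytokines and chemokines had a median of −0.38 (adjusted p = 0.026; adjusted p = 0.503 with an estimated correlation; 7 of 30), with the monocyte attractants Ccl7 at −1.50 (SE 0.33, adjusted p = 0.228) and Ccl2 at −1.13 (SE 0.30). This call was lost without G0 replicate 2 or 4 or G1 replicate 1 or 4 (adjusted p = 0.152, 0.556, 0.073 and 0.611), in labelling batch 1 alone (0.558) and on the 6 arrays with spike-ins (0.116). Interferon-stimulated genes had a median of −0.38 (adjusted p = 0.026; adjusted p = 0.503 with an estimated correlation; 3 of 25), with Gbp2 at −1.03 (SE 0.34) and Stat2 at −0.76 (SE 0.24). That call was lost without G0 replicate 1 or G1 replicate 3 (adjusted p = 0.166 and 0.106), with the spike-in batch as covariate (0.070), on the 6 arrays (0.172), with plain _at probe sets alone (0.078) and with the quietest probe set (0.093). Within the labelled batches the medians of the 4 lists in this order were −0.33 and −0.04, −0.39 and −0.30, −0.34 and −1.36, and −0.52 and 0.09. Within the spike-in batches they were −0.23 and −0.22, −0.34 and −0.19, −0.31 and −0.50, and −0.40 and −0.42.

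No list of markers of another cell type passed as a group. The median log2 difference was −0.19 for leukocyte markers (17 genes; camera, adjusted p = 0.455), 0.44 for epithelial markers (16 genes, adjusted p = 0.189), −0.11 for endothelial markers (12 genes, adjusted p = 0.543) and 0.08 for muscle and adipocyte markers (13 genes, adjusted p = 0.668). Fry passed for 7 of the 27 lists. These were G2 and mitosis (adjusted p = 0.00031), replication licensing and S phase (0.00031), nucleotide synthesis (0.0033), D-type and E-type cyclins (0.014), E2F and DREAM genes (0.026) and p27 degradation (0.028), all placed higher, and growth arrest genes (0.048), placed lower. Its mixed form passed for the same lists and for the endothelial markers (adjusted p = 0.028), whose members went in both directions. The lists with no shift past the threshold also included cytosolic ribosomal proteins (0.13, adjusted p = 0.118), translation factors (0.10, adjusted p = 0.164), the respiratory chain (0.05, adjusted p = 0.189) and glycolysis (0.005, adjusted p = 0.686). Cholesterol synthesis (−0.10, adjusted p = 0.543), p53 targets (−0.26, adjusted p = 0.145), heat shock (0.05, adjusted p = 0.771), YAP and SRF targets (−0.06, adjusted p = 0.543) and the circadian clock (−0.26, adjusted p = 0.222) did not pass either. Camera put glycolysis and heat shock on the lower side, against the sign of their medians. Without G0 replicate 2, ribosomal proteins (adjusted p = 0.014) and translation factors (adjusted p = 0.028) passed as higher. Ribosomal proteins also passed with the quietest probe set (adjusted p = 0.0050) and with the spike-in batch as covariate (adjusted p = 0.049, but 0.628 with an estimated correlation).

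**Figure D3:**
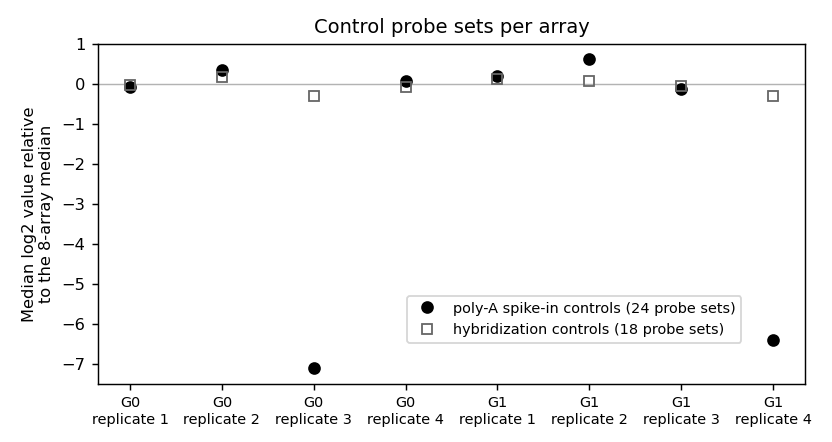
Median log2 value of the control probe sets on each array relative to the 8-array median (vertical axis). Filled circles are the poly-A spike-ins added to total RNA, and open squares the hybridization controls added to labelled cRNA. The spike-ins lie at −7.12 on the array titled G0 replicate 3 and at −6.40 on G1 replicate 4, and between −0.14 and 0.62 on the other 6.

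No measure of RNA or labelling quality differed past the threshold between G0 and G1. This is weak evidence of equal quality. With 4 arrays per group a single measure could not pass once adjusted over all measures, even with the groups fully apart. The log2 ratio of the 3′ to the 5′ control probe sets relative to the 8-array median was −0.18 ± 0.40 in G0 and −0.19 ± 0.41 in G1 for Actb (SD, n = 4; exact permutation test, two-sided, p = 1). For Gapdh it was −0.08 ± 0.12 and −0.003 ± 0.11 (exact permutation p = 0.371). The array titled G0 replicate 3 and G1 replicate 4 stood apart from the rest in the poly-A spike-ins, and also had the lowest Actb ratios (−0.78 on both) and 18S rRNA controls (−5.70 and −5.57).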

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

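The counts over splits of the arrays and the test of scaling were fixed before the results were seen, and the tests of the spike-in batch, of transcripts of S phase to mitosis, of exchanged numbers, of omitted spike-ins and of G1 RNA on a G0 array were chosen after the results were seen.

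The poly-A spike-ins, which the comparisons do not use, had a median of −7.11785 on the array titled G0 replicate 3 and of −6.40217 on G1 replicate 4, against −0.14 to 0.62 on the other 6. The labels put G0 replicate 4 and G1 replicate 4 in the batch with its own labelling protocol. RNA of the G1 gate on the array titled G0 replicate 3 is argued against by its G2 and mitosis median of −0.937, which lay near the other G0 arrays (−1.51 to −1.03) and below all G1 arrays (0.86 to 1.52). An omission of the spike-ins with no other difference in labelling is argued against by the 18S rRNA controls, at −5.70 on that array and −5.57 on G1 replicate 4 against −0.44 to 0.48 elsewhere. The 5′ control of Tfrc was also apart, at 3.80 and 4.27 against −0.73 to 0.38. An exchange of the numbers 3 and 4 within G0 was not separated from correct numbers with a wrong protocol in the labels. The exchange was proposed after the values were seen, so they cannot decide for it. In the order of the deposited samples, G0 replicate 4 stands before G0 replicate 3, while the G1 arrays follow their numbers. Either reading would give the spike-in value of −7.12. If arrays labelled alike resemble each other, either would also give the deviations of G0 replicate 3, which correlated best with G1 replicate 4 (r = 0.309 across probe sets, which are not independent). Shared labelling does not give the best match of G0 replicate 4 with G1 replicate 3 (r = 0.10, against 0.027 and 0.026 with G1 replicates 1 and 2). An exchange would give it if equal numbers belong together, and G0 replicates 1 and 2 did correlate best with their own number. These correlations are small and do not settle it. No biological explanation was tested.

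The G2 and mitosis list was higher in G1 by a median of 2.32. Of the 35 splits of the 8 arrays into 2 groups of 4, 1 reached it, the real one (at most 1.88 in another split). That is the smallest share this test can give. Some splits put both arrays without spike-ins in the same group, unlike the real one. Splits kept balanced are too few for the share to fall under 0.05, so chance is not excluded at 0.05. The splits also describe only these samples, which may be technical replicates. Scaling between arrays is argued against by a median of 2.39 after quantile normalization, although array medians spanned only 0.16, so scaling had little to change. Each batch that the spike-ins show holds equal numbers of both groups, so a shift common to a batch could not by itself make the difference. The medians of 2.27 in the 6 arrays with spike-ins and 2.41 in the 2 without therefore decide nothing more about the labelling batch. The list rose by 1.11 more than the replication licensing and S phase list, a comparison made after both medians were seen, which decides nothing. Cells in the G1 gate that carried transcripts of S phase to mitosis therefore stay open, either as remnants of a recent division or as cycling cells inside the gate, although a gate on the Cdt1 fragment should remove cells from S phase on. A regulated difference between G0 and G1 cells, which the design names, stays open too and was not tested. These cannot be told apart, because the arrays hold RNA of sorted populations and give no value per cell.

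The same limits hold for the counts, for which chance is not excluded either once the batches are kept balanced. Of the 35 splits, 1, the real one, gave as many genes changed (95, at most 2 in another split) and probe sets changed (180, at most 5). The same held for genes in the more frequent direction (91, at most 1) and in the less frequent one (4, at most 1). It also held for genes changed at least 2-fold (95, at most 2), which are the same 95 genes. For the replication licensing and S phase list it was also 1 of 35 (1.20, at most 0.98). For the other lists tested, chance cannot be excluded even over all 35 splits. As large a median came from 20 splits for D-type and E-type cyclins (0.04, at most 0.30 in another split), from 4 for CDK inhibitors and Rb family genes (0.57, at most 0.78), from 10 for immediate early genes (0.25 in size, at most 0.54), from 4 for growth arrest genes (0.36 in size, at most 0.46) and from 20 for ribosome biogenesis (0.09, at most 0.32).

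In 11 of 180 groups of 4 arrays a single array lay far from the other 3, where chance gives about 5%. Of these, 3 were on the array titled G0 replicate 3 and 4 on G1 replicate 4. On G0 replicate 1, 2410003I16Rik stood at −1.25877 (others tied at −2.20, as at a floor, so their spread is not known) and 4930503B20Rik at −0.694082 (others −1.79 to −1.67). On G0 replicate 3, Ccne1 stood at −1.04213 (others −0.45 to −0.37), Ccnd2 at 0.921636 (others −0.06 to 0.10) and Dusp1 at 0.737995 (others 0.07 to 0.11). On G0 replicate 2, Rbl1 stood at −0.883075 (others −0.25 to −0.15). On G1 replicate 4, Ccnd2 stood at 0.609543 (others −0.27 to −0.22), and list medians stood at 1.02722 for CDK inhibitors and Rb family genes (others −0.08 to 0.10), at 0.23344 for p27 degradation (others −0.003 to 0.03) and at 0.161468 for lysosome genes (others −0.15 to −0.12). On G1 replicate 1 the extracellular matrix median stood at −0.272636 (others −0.09 to −0.06).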

How the results depend on the processing

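Alternatives were fixed before the data were examined, except the spike-in batch, the 6 arrays with spike-ins, the robust variance model and the quietest probe set, which were chosen after the data were seen. Pseudocounts and other level filters were not run, since the values were already logs and centred, and centring also hides what signal over background limits. Under 14 alternatives and with each array left out, 23 of the 24 named genes past the threshold and 10 of the 11 lists past it kept their sign. The exceptions were Galns and p27 degradation. All 24 genes separate the groups completely, so leaving out an array or changing the covariate or variance model could not turn their sign. Under those settings the count of genes that kept their sign is no test of stability. The cause of a change was not tested, except that fewer arrays or probe sets enter some fits by construction.

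The count of 95 genes depended on which arrays entered and on the error estimate. With the spike-in batch in the model 183 genes (169 higher, 14 lower, 176 by at least 2-fold) and 355 probe sets passed, and the ribosome biogenesis median of 0.089 and ribosomal proteins passed too, while interferon-stimulated genes (adjusted p = 0.070) and 1 of the 24 named genes past the threshold no longer did. Without the 2 arrays that lack spike-ins it was 31 genes (30 higher, 1 lower, 31 by at least 2-fold) and 44 probe sets. Calls were lost there for p27 degradation, cytokines, interferon-stimulated genes and 15 of the 24 named genes. There the median of the D-type and E-type cyclins was −0.021, that of glycolysis −0.040, the difference of Ccnd1 −0.037 and that of Cdkn2c −0.039. In labelling batch 1 alone, with 3 arrays per group, 0 genes and 0 probe sets passed in limma, so 0 were higher, lower or changed by 2-fold (1596 genes at an unadjusted p under 0.05). CDK inhibitors (median 0.30, adjusted p = 0.218), p27 degradation (adjusted p = 0.137), extracellular matrix (0.111) and cytokines (0.558) no longer passed there, and the ribosome biogenesis median was 0.18 and passed. Glycolysis (−0.044), heat shock (−0.014) and YAP and SRF targets (0.092) changed sign. Without a labelling batch 9 genes were lower and 138 passed in all, and with the robust variance model 10 were lower and 122 passed. The other 6 planned settings gave 74 to 113 genes, and the quietest probe set 126. Of the 24 named genes past the threshold, calls were lost for 5 after quantile normalization (Bard1, E2f7, Rrm1, Prim2 and Lig1), 3 with the robust variance model (Bard1, Lgi4 and Odam) and 1 without a variance trend (Melk). Cks2 passed without a labelling batch and with the robust variance model.

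By the titled numbers the replicates did not pair. The deviations from the group means correlated at 0.07, 0.11, −0.14 and −0.14 for numbers 1 to 4, and arrays 3 and 4 correlated better with another number than with their own. With numbers 3 and 4 of G0 exchanged the correlations would be 0.07, 0.11, 0.31 and 0.10. The block was run with the titled numbers only. With the replicate block, which spends more degrees of freedom, 0 genes passed in limma (1456 at an unadjusted p under 0.05), 0 higher, 0 lower, 0 by 2-fold, and 0 probe sets. The p27 degradation list lost its call too (adjusted p = 0.064).

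With an estimated correlation, 8 of the 11 lists past the threshold no longer passed. These were CDK inhibitors (median 0.57), growth arrest (−0.36), E2F and DREAM genes, p27 degradation, lysosome, extracellular matrix, cytokines and interferon-stimulated genes. The p27 degradation median, −0.02, became 0.025 after quantile normalization, 0.0026 with arrays centred on their medians, 0.038 with array weights and 0.027 with the quietest probe set. Its camera call was lost in the last 2 of these (adjusted p = 0.057 and 0.093). Array weights also gave −0.0034 for the D-type and E-type cyclins and for Cdk6, −0.0059 for Ccnd1 and −0.063 for glycolysis. When the tests ran on plain _at probe sets alone, 105 probe sets passed, interferon-stimulated genes (adjusted p = 0.078) and Odam no longer did, and glycolysis (−0.12), endothelial (0.076) and muscle and adipocyte markers (−0.028) changed sign. With the mean of all probe sets of a gene, 22 of the 95 genes lost their call, among them Esco2, 4930503B20Rik, Galns, E2f8, Rrm1 and Prim2, while Ccne1 passed. The differences of those that lost it were, in this order, 3.34, 1.29, −1.79, 2.23, 0.87 and 1.23 (limma, adjusted p = 0.051, 0.419, 0.056, 0.406, 0.736 and 0.183). CDK inhibitors (0.46, adjusted p = 0.079) and p27 degradation (adjusted p = 0.114) no longer passed, and signs changed for the D-type and E-type cyclins and Ccnd1 (both −0.012), Ccnd3 (−0.041), Ctso (0.079), translation factors (−0.0019), glycolysis (−0.045), heat shock (−0.018) and endothelial markers (0.12). The quietest probe set turned Galns (0.30), glycolysis (−0.098), leukocyte (0.029) and endothelial markers (0.22). Interferon-stimulated genes (adjusted p = 0.093) and Galns no longer passed there, and ribosomal proteins did.

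With single arrays left out, 0 to 67 genes passed in limma, 0 to 67 of them higher, 0 to 67 by at least 2-fold and none lower in any of the 8 fits, and 0 to 122 probe sets. The medians ran from −0.18 to 0.18 for D-type and E-type cyclins, 0.14 to 0.75 for CDK inhibitors, −0.062 to 0.11 for p27 degradation, −0.33 to −0.12 for immediate early genes, 0.010 to 0.18 for ribosome biogenesis, −0.19 to 0.070 for cholesterol synthesis, −0.11 to 0.030 for glycolysis, −0.014 to 0.053 for heat shock and −0.22 to 0.14 for YAP and SRF targets. Ccnd1 ran from −0.24 to 0.25 and Cdk6 from −0.32 to 0.35, and Cdkn2c was −0.038 without G0 replicate 1. The G2 and mitosis median stayed between 2.19 and 2.38, and that of replication licensing and S phase between 1.14 and 1.28.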

Other observations

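The gene families below were chosen after the called genes were seen, as were the single immediate early genes and the lower genes named last. They describe the data and test no explanation.

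Several genes of the kinetochore, condensin and augmin were among those higher in G1, and some of them, such as Cenpf and Cenpe, were members of the G2 and mitosis list. No family was tested for enrichment. Of 21 measured genes named Cenp, the proteins of the centromere, 10 were higher in G1 and 0 lower in limma, and all 21 had positive differences, with a median of 1.88 (1.92 after quantile normalization). Cenpf was higher by 2.78 (SE 0.24, adjusted p = 0.010) and Cenpe, a kinetochore motor, by 2.42 (SE 0.27, adjusted p = 0.020). The 6 Ncap genes, subunits of condensin, which compacts mitotic chromosomes, had a median of 2.07, and 3 of them rose: Ncapg by 3.04 (SE 0.24), Ncapg2 and Ncapd2. The 8 Haus genes of the augmin complex, which branches spindle microtubules, had a median of 1.15, with Haus4 and Haus8 higher.

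Of 37 Kif genes (kinesin motors), 5 rose and the median was 0.06 (0.09 after quantile normalization). These were the mitotic kinesins Kif11, Kif18b, Kif20a, Kif22 and Kif4. Of 10 Fanc genes, which repair DNA crosslinks, Fancb rose and the median was 0.71. Of 7 Cdca genes, 2 rose (Cdca5 and Cdca8), with a median of 0.79.

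The immediate early genes Fos and Egr1 varied more between arrays of the same gate than between the gates. The list's other members were not counted in this way. Of them, Dusp1 differed by −0.77 (SD 0.32 in G0 and 0.31 in G1) and Klf10 by −0.49 (SD 0.19 and 0.12). Fos stood at 1.77, −0.44, 1.70 and −1.17 in the G0 arrays 1 to 4 and at 1.77, −0.61, −1.51 and 0.44 in the G1 arrays. It was thus positive on array 1 of both gates and on the array of each gate without spike-ins, and negative on all others. Egr1 was highest on replicate 1 of both groups, at 1.61 in G0 and 2.37 in G1, and stood between −1.33 and 0.47 on the other 6 arrays. Part of the variation within a gate therefore ran alike in both gates and cannot be read as separate scatter of single arrays. Pairing of arrays across the gates was not tested for these genes.

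With the spike-in batch as covariate, 14 genes were lower in G1. Besides Galns, Lgi4 and Odam they included Ccnb3, a meiotic cyclin B (−3.02, adjusted p = 0.018), Vldlr, a lipoprotein receptor (−2.18, adjusted p = 0.041), Saa3, an acute phase protein (−1.84, adjusted p = 0.022), and Kdm5b, a histone H3 lysine 4 demethylase (−1.59, adjusted p = 0.034). With the labelled batch Ccnb3, Vldlr, Saa3 and Kdm5b had adjusted p = 0.072, 0.078, 0.226 and 0.437. Under the spike-in batch 0 genes passed in limma once G1 replicate 1, 3 or 4 was left out (2090, 1938 and 1677 at an unadjusted p under 0.05).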
